A study of Rattus norvegicus with 21 samples.

How the data were processed

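Neonatal rat ventricular myocytes were profiled in 20 RNA sequencing libraries and 1 CUT&Tag library. The RNA libraries fell into 8 groups by the sample labels: siNeg and siKlf2 with and without PE (2 libraries each), and AdGFP and AdKlf2 with and without PE (3 libraries each). Per the labels' protocols, libraries were made from 400 ng of total RNA. Per the submitters' processing notes, the authors trimmed reads with Trim Galore, aligned them with STAR and counted them with featureCounts on the rat build mRatBN7.2, with no versions given. The 2 deposited tables hold raw counts per Ensembl gene ID, 1 table for knockdown and 1 for overexpression, with 30560 IDs in each. The values were whole numbers with a different total in each library, 181101876 to 224082309 in the knockdown table and 32693762 to 76138723 in the overexpression table. Among counts of 1 to 20, even values made up 59.8% to 66.6% in the knockdown table and 72.1% to 82.2% in the overexpression table, so many fragments appear to have been counted at both mates, and a count is not an independent fragment. The deposited peak list gives for each peak a score, a fold enrichment (a ratio to a background not given in the sources used here), and −log10 p and q values. The peak caller and any control library are not given in those sources.

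Each table was analysed with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr with a minimum count of 10 and a minimum total of 15, which left 18173 genes in the knockdown table and 16153 in the overexpression table. Libraries were scaled with TMM factors, and all 4 groups of a table entered 1 quasi-likelihood fit with a coefficient per group. Each table gave 5 contrasts, which were KLF2 level without PE, KLF2 level with PE, PE in each arm, and the interaction. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the genes of a contrast, and a gene was called at an adjusted p under 0.05. Levels are given in CPM, counts divided by the library total scaled with its TMM factor. The biological coefficient of variation was 0.049 in the knockdown table and 0.132 in the overexpression table. Tested on simulated data with 200 changed genes, the procedure recovered 65% and 61% of 1.5-fold changes in the 2 designs, with 5.96% and 4.93% false calls. Apart from those changes, the simulation gave each gene the same mean and spread in every group. It therefore does not cover comparisons where groups differ in spread, as AdGFP without PE did, or where many genes change.

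Genes called for PE in a control arm of one table were tested as lists in the KLF2 contrasts of the other table, which shares no libraries with it. Genes called for AdKlf2 were also tested as lists in siKlf2. The camera test of limma 3.58.1 used a preset correlation of 0.01, with adjustment over 16 set tests per fold minimum. Each was repeated with a correlation estimated from the data. Fold changes of both tables were compared over 15944 genes tested in both, with Spearman correlations across genes. Overlaps of genes called with a fold of at least 1.5 were tested with Fisher's exact test, two-sided, adjusted over all overlaps. These contrasts, the tests of PE lists in the KLF2 contrasts with PE, and the correlations were chosen before the data were examined. Set tests without PE, on the interaction or of AdKlf2 genes were chosen afterwards. So were the responses of lists by arm, the genes at 0 in a whole group and the other overlaps.

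The IDs had no gene symbols in the reference used here, where 0 of them matched. For that reason the 30 gene lists fixed beforehand, the rule for named genes, the tests of peaks at promoters and the search for a binding motif at peak summits were not run. In place of that rule, chosen after the values were seen, 4 IDs were followed. These had the 2 largest mean rises and the 2 largest mean falls with PE over both control arms, among genes called in both, with a mean of at least 5 CPM and with groups that did not overlap, which chance gives for 10% of genes with 3 libraries against 3.

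Alternatives were RLE size factors, no filter, DESeq2 1.42.0, a replicate block, fits of only the 2 compared groups, a minimum fold of 1.5 and leaving out each library in turn. Added after the data were seen were library totals without TMM factors, limma voom with quality weights, counts halved, a minimum of 10 CPM and fry. When a group was left with 1 library, that library was taken to vary like those of the other groups. Other regroupings of the libraries were run for the comparisons of 3 against 3. Same-numbered libraries of different groups did not pair, with correlations of their deviations of -0.0432 to 0.0403 and -0.0203 to 0.0446 in the knockdown and overexpression tables. Tables of counts per library were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9.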

Results

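RNA sequencing was used to profile neonatal rat ventricular myocytes (NRVMs), primary heart muscle cells cultured from newborn rats, in which the level of the zinc finger transcription factor KLF2 had been lowered or raised. Knockdown used a small interfering RNA against Klf2 (siKlf2) with a negative control (siNeg), and overexpression used an adenovirus carrying Klf2 (AdKlf2) with a green fluorescent protein virus as control (AdGFP). Both manipulations were made with and without phenylephrine (PE), an α1-adrenergic agonist that induces hypertrophic growth of cultured cardiomyocytes, labelled at 100 µM for 36 h. The small interfering RNA was given 12 h before PE, whereas the virus was given for 24 h after the first 12 h with or without PE. The knockdown table held 4 groups of 2 libraries and the table for overexpression held 4 groups of 3 libraries. A further library came from CUT&Tag, an assay that cuts and tags chromatin at the sites bound by a protein, in KLF2-overexpressing NRVMs.

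Total counts per library were 181101876 to 224082309 in the knockdown table and 32693762 to 76138723 in the overexpression table. Replicates of the knockdown groups correlated at 0.995 to 0.9957 in log CPM across genes, and those of the AdKlf2, AdGFP with PE and AdKlf2 with PE groups at 0.982 to 0.9915. The 3 AdGFP libraries without PE stood apart, with correlations of 0.959 to 0.965. They held 539 to 776 genes with 1 to 5 counts, against 1728 to 2022 in the other libraries of the table, at totals of 53623078 to 60994028 counts. In that group 188 genes were at 0 in one library and at 50 counts or more in another, against at most 10 in any other group. The labels do not say whether replicates came from separate cell preparations, so p-values measure the spread between these libraries, which may be technical. Genes were listed by Ensembl ID without symbols, and 4 IDs are followed here through all comparisons. The level of Klf2 itself was not analysed here, so neither its knockdown nor its overexpression was checked.

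**Figure D1:**
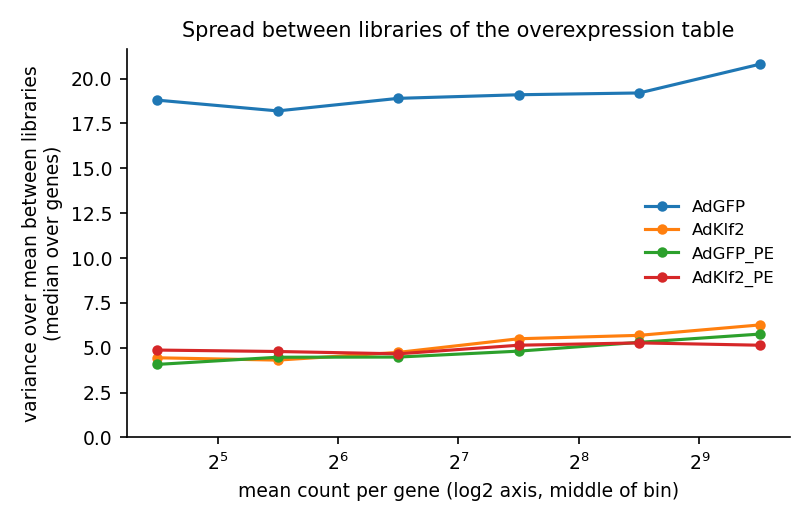
Median ratio of variance to mean between replicate libraries (vertical axis) against the mean count of genes (horizontal log axis) in the overexpression table, with a line per group. At a mean of 16 to 64 counts the AdGFP group without PE lies at 18.6 and the other groups of its table at 4.23 to 4.84.

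The response of control cells to PE was compared in both tables. In siNeg cells PE raised 1074 genes and lowered 1449 by a fold of at least 1.5, and in AdGFP cells it raised 1026 and lowered 1228. Among genes with a mean of at least 10 CPM the split was the reverse, with 530 higher and 426 lower in siNeg and 658 higher and 594 lower in AdGFP, so the excess of lower genes lay among genes of low level. Of 15944 genes tested in both tables, 533 rose in both, against 63.7 for independent lists of these sizes, and 637 fell in both, against 104. Of the 1179 genes called in both tables at this fold, 1170 moved in the same direction. Among the rises in both tables, ENSRNOG00000008141 went from 32.2 ± 0.117 to 790.4 ± 95.3 CPM in siNeg (SD, n = 2) and from 12.8 ± 4.18 to 600.3 ± 24.5 CPM in AdGFP (SD, n = 3). ENSRNOG00000008176 went from 182.5 ± 0.91 to 2885 ± 184 CPM in siNeg (SD, n = 2) and from 95 ± 12.4 to 3708 ± 98.4 CPM in AdGFP (SD, n = 3). Their log2 fold changes were 4.62 (SE 0.077) and 3.98 (SE 0.047) in siNeg, with adjusted p of 1.25e-11 and 2.21e-12 in edgeR's quasi-likelihood test. Among the falls, ENSRNOG00000019120 went from 38.3 ± 0.52 to 9.02 ± 1.36 CPM in siNeg (SD, n = 2) and from 40.8 ± 0.431 to 4.82 ± 0.306 CPM in AdGFP (SD, n = 3). ENSRNOG00000012442 went from 113 ± 5.01 to 31.1 ± 3.92 CPM in siNeg (SD, n = 2) and from 162 ± 15.1 to 19.9 ± 2.1 CPM in AdGFP (SD, n = 3).

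With no minimum fold, 8922 of 18173 tested genes passed in siNeg (4512 higher, 4410 lower) and 5588 of 16153 in AdGFP (2958 higher, 2630 lower). The 2 sets of fold changes had a Spearman correlation of 0.632 across genes, which are not independent replicates, and of 0.784 among the 8777 genes with a mean of at least 10 CPM in both tables. Scaling by library totals alone, without TMM factors, changed the share of called genes that were higher from 50.6% to 33.2% in siNeg and from 52.9% to 30.1% in AdGFP. The AdGFP comparison rests on the AdGFP libraries without PE described above.

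**Figure D2:**
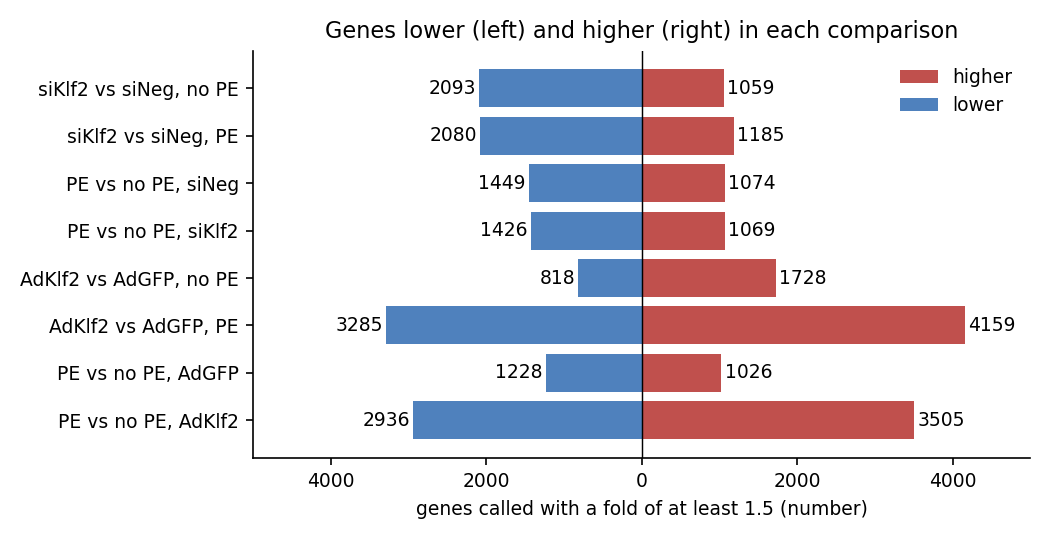
Number of genes called by edgeR's quasi-likelihood test with a fold of at least 1.5 in each of 8 comparisons, lower genes to the left and higher genes to the right (horizontal axis, number of genes). The longest bars are those of AdKlf2 against AdGFP with PE, 4159 higher and 3285 lower.

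Whether loss of KLF2 alters the transcriptome of resting and PE-treated myocytes was asked by comparing siKlf2 with siNeg. Without PE, knockdown raised 1059 genes and lowered 2093 by a fold of at least 1.5, and with PE it raised 1185 and lowered 2080. The excess of lower genes lay among genes of low level, since at a mean of at least 10 CPM 598 were higher and 411 lower without PE, and 656 higher and 415 lower with PE. Of all genes called with a fold of at least 1.5, 677 rose in both comparisons and 1349 fell in both, while 12 moved in opposite directions. The knockdown libraries with and without PE are separate, and their fold changes had a Spearman correlation of 0.716 across genes. Both PE-induced IDs were higher after knockdown. They were chosen partly for a low level in siNeg without PE, so their rise without PE is partly built into the choice. ENSRNOG00000008141 reached 453 ± 26.8 CPM in siKlf2 without PE (SD, n = 2), a log2 fold change of 3.82 (SE 0.075, edgeR adjusted p = 3.63e-11), and 2049 ± 12.5 CPM with PE (SD, n = 2), a log2 fold change of 1.37 (SE 0.067, edgeR adjusted p = 1.99e-08). ENSRNOG00000008176 rose by 3.57 on the log2 scale without PE (SE 0.046, edgeR adjusted p = 2.9e-12) and by 1.79 with PE (SE 0.043, edgeR adjusted p = 1.56e-10). The PE-lowered ENSRNOG00000019120 was higher by 0.64 on the log2 scale without PE (SE 0.07, edgeR adjusted p = 1.32e-05), and its log2 fold change with PE was 0.04 (SE 0.079, edgeR adjusted p = 0.703). The latter was 0.21 without siNeg with PE replicate 1 (edgeR adjusted p = 0.00556) and -0.23 with scaling by library totals alone. ENSRNOG00000012442, chosen partly for a high level in siNeg without PE, had log2 fold changes of -0.24 without PE (SE 0.08, edgeR adjusted p = 0.0254) and 0.20 with PE (SE 0.084, edgeR adjusted p = 0.0622). The first call was lost without siNeg replicate 2 (edgeR adjusted p = 0.147) or siKlf2 replicate 1 (edgeR adjusted p = 0.206). The second was gained without replicate 1 of siNeg with PE (edgeR adjusted p = 0.00275) or of siKlf2 with PE (edgeR adjusted p = 0.0238).

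Genes that responded to PE in AdGFP cells, lists taken from the other table, had medians after knockdown in the direction of their PE response, and not every list test held with an estimated correlation. Of 2949 genes raised by PE in AdGFP, 455 rose and 175 fell by a fold of at least 1.5 in siKlf2 with PE, and their median log2 fold change was 0.14, against -0.08 for other genes. Camera gave an adjusted p of 1.68e-10, and adjusted p = 0.00867 with an estimated correlation. That estimate was 0.00617, under the preset 0.01, so the larger p did not come from a higher correlation. A call lost with an estimated correlation is therefore not by itself evidence of correlated genes. For the 1017 genes of the list with a fold of at least 1.5 the median was 0.20, and camera gave an adjusted p of 4.2e-12, which was lost with an estimated correlation (adjusted p = 0.0598). Without PE the same list had a median of 0.18, with 407 genes higher and 149 lower (camera adjusted p = 2.25e-11, and adjusted p = 0.00867 with an estimated correlation). With a fold of at least 1.5 that call too was lost with an estimated correlation (adjusted p = 0.0598). Of 2628 genes lowered by PE in AdGFP, 89 rose and 462 fell in siKlf2 with PE, with a median of -0.16 against -0.02 for other genes (camera adjusted p = 0.00033). This call was lost with an estimated correlation (adjusted p = 0.125). Without PE, 82 rose and 470 fell, with a median of -0.14 (camera adjusted p = 8.42e-05, and adjusted p = 0.125 with an estimated correlation).

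Over all tested genes, 9802 passed without PE (4934 higher, 4868 lower) and 9866 with PE (4750 higher, 5116 lower). Scaling by library totals alone, without TMM factors, changed the split to 21.9% higher without PE and 15.9% with PE, from 50.3% and 48.1%, so small changes of direction depend on the scaling.

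Whether knockdown changed the response to PE itself was tested with the interaction of both factors. PE raised 1069 genes and lowered 1426 by a fold of at least 1.5 in siKlf2 cells, close in number to siNeg cells, and 523 were higher and 440 lower among genes of at least 10 CPM. The interaction was called for 2622 genes, 1287 with a higher and 1335 with a lower PE response after knockdown, of which 447 differed by a fold of at least 1.5. With library totals alone, the share higher was 24.2% rather than 49.1% for the interaction, and 23.6% rather than 50.8% for PE in siKlf2. For both PE-induced IDs the PE response was smaller in siKlf2, from a higher level without PE. These IDs were chosen for large PE responses in the control arms, so a smaller response in the other arm is partly built into the choice. The PE response of ENSRNOG00000008141 was lower by 2.44 on the log2 scale (log2 difference -2.44, SE 0.095, edgeR adjusted p = 2.93e-07) and that of ENSRNOG00000008176 by 1.78 (log2 difference -1.78, SE 0.059, edgeR adjusted p = 1.61e-07). As a list, the PE-raised genes of AdGFP with a fold of at least 1.5 had median log2 fold changes of 0.62 in siNeg and 0.64 in siKlf2 over 1017 genes, but members went both ways. Their interaction was called higher for 161 genes and lower for 180, while 14.4% of all tested genes had a called interaction. Camera, which tests for a shift in 1 direction, gave an adjusted p of 0.548. The number of interaction calls moved both down and up when a library was left out. Each such fit keeps 1 library in a group, so a loss of calls may come from fewer libraries rather than from a particular one.

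**Figure D3:**
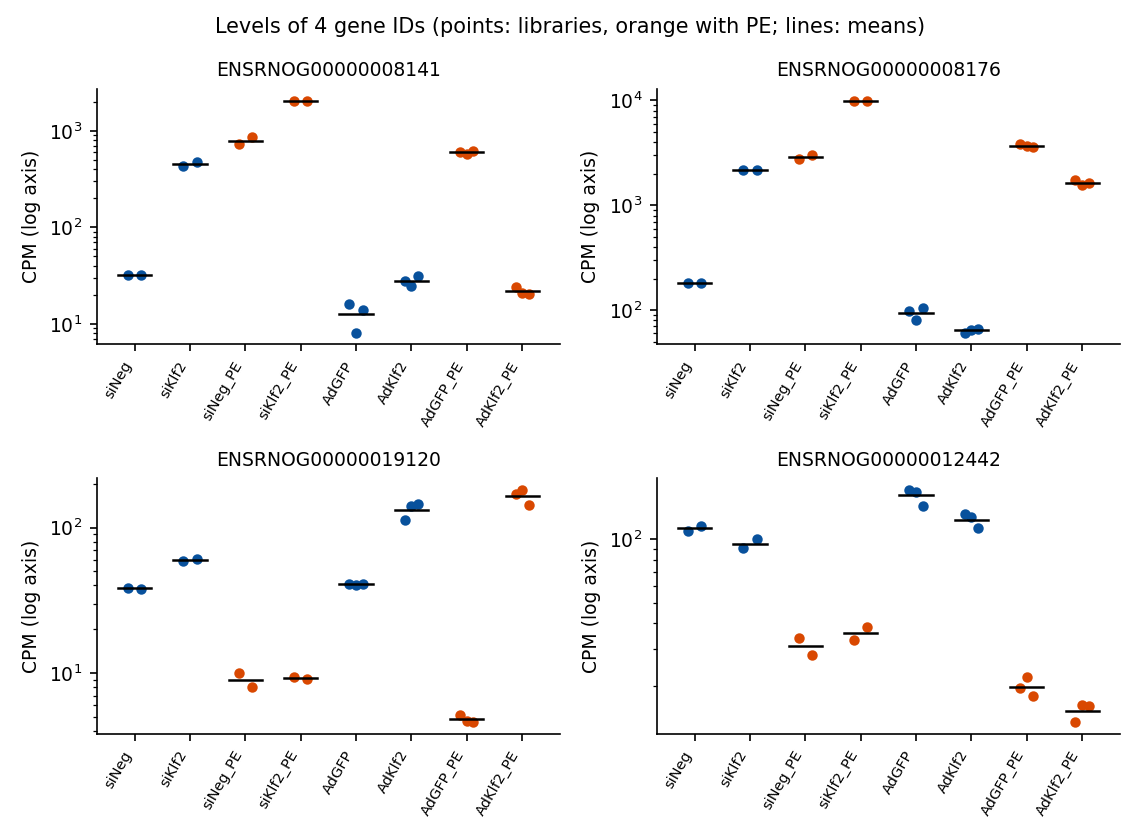
Normalized level of 4 gene IDs in CPM (vertical log axis) in the 8 groups of both tables, with a point per library (orange with PE, blue without) and a line at the group mean. ENSRNOG00000008141 lies at 600.3 CPM in AdGFP with PE and at 21.8 CPM in AdKlf2 with PE.

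Overexpression of KLF2 was compared with AdGFP to ask whether added KLF2 alters the same cells. Without PE, AdKlf2 raised 1728 genes and lowered 818 by a fold of at least 1.5. With PE it raised 4159 genes and lowered 3285. Of the genes called at this fold, 1414 rose in both comparisons, 546 fell in both and 113 moved in opposite directions. A fold of at least 4 was reached by 685 higher and 40 lower genes without PE, and by 1866 higher and 617 lower genes with PE. The 2 PE-induced IDs, chosen partly for their high level in AdGFP with PE, were lower in AdKlf2 with PE. ENSRNOG00000008141 lay at 21.8 ± 2.22 CPM (SD, n = 3), a log2 fold change of -4.78 against AdGFP with PE (SE 0.165, edgeR adjusted p = 8.03e-15). Without PE it was higher by 1.13 (SE 0.159, edgeR adjusted p = 1.39e-05), against an AdGFP level chosen partly for being low. ENSRNOG00000008176 lay at 1648 ± 101 CPM with PE (SD, n = 3), a log2 fold change of -1.17 (SE 0.071, edgeR adjusted p = 3.38e-11), and without PE its log2 fold change was -0.56 (SE 0.073, edgeR adjusted p = 5.76e-06). The PE-lowered ENSRNOG00000019120, chosen partly for its low level in AdGFP with PE, was higher in AdKlf2, by 1.70 on the log2 scale without PE (SE 0.094, edgeR adjusted p = 5.9e-11) and by 5.10 with PE (SE 0.119, edgeR adjusted p = 3.34e-17). ENSRNOG00000012442, also lowered by PE and chosen partly for a high level in AdGFP without PE, was lower in AdKlf2 in both comparisons, with log2 fold changes of -0.38 and -0.38.

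With no minimum fold, 5672 genes passed without PE (3225 higher, 2447 lower) and 10625 with PE (5435 higher, 5190 lower). Both the comparison without PE and the PE response of AdGFP use the 3 AdGFP libraries that stood apart. The fold changes with PE do not, although those libraries enter the spread shared by all groups of the fit. AdKlf2 libraries with PE also had the lowest share of counts in their 10 most abundant genes, 7.36% ± 0.275 (SD, n = 3), against 11% ± 0.493 in AdGFP with PE (SD, n = 3).

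A set of 73 genes had 0 counts in all 3 AdGFP libraries with PE and at least 1 CPM in each AdKlf2 library with PE. Their median level in AdKlf2 with PE was 2.85 CPM and the highest 484 CPM. All 73 stayed under 1 CPM in every library of the knockdown table, and 15 of them also reached 1 CPM in each AdKlf2 library without PE. In the other direction, 1 gene had 0 counts in AdKlf2 with PE and at least 1 CPM in each AdGFP library with PE. No fold is given for these genes, because fragments may have been counted at both mates and 0 counts then set no exact limit.

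The response to PE differed between AdKlf2 and AdGFP cells. PE raised 3505 genes and lowered 2936 by a fold of at least 1.5 in AdKlf2, and with no minimum fold 9895 genes passed (5112 higher, 4783 lower). With library totals alone, 39.2% of the called genes were higher, rather than 51.7%. The interaction was called for 7926 genes (4050 higher, 3876 lower), 5671 of them with a fold of at least 1.5. Of the interaction genes, 46.9% were higher with library totals alone, rather than 51.1%. Genes raised by PE in siNeg cells, a list taken from the other table, had a smaller PE response in AdKlf2. Over 984 such genes with a fold of at least 1.5, the median PE response was 0.83 on the log2 scale in AdGFP (quartiles 0.47 and 1.35) and 0.26 in AdKlf2 (quartiles -0.46 and 1.18). The response was called lower in AdKlf2 for 451 of them and higher for 142, and camera on the interaction gave an adjusted p of 2.32e-09, with adjusted p = 0.0343 with an estimated correlation. PE raised 654 of these genes significantly in AdGFP and 406 in AdKlf2, and lowered 221 in AdKlf2. For 1340 genes lowered by PE in siNeg the medians were -0.82 in AdGFP and -0.68 in AdKlf2. The response of these genes was called higher for 413 and lower for 241, and camera gave an adjusted p of 0.109. Every interaction value includes the AdGFP libraries without PE.

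**Figure D4:**
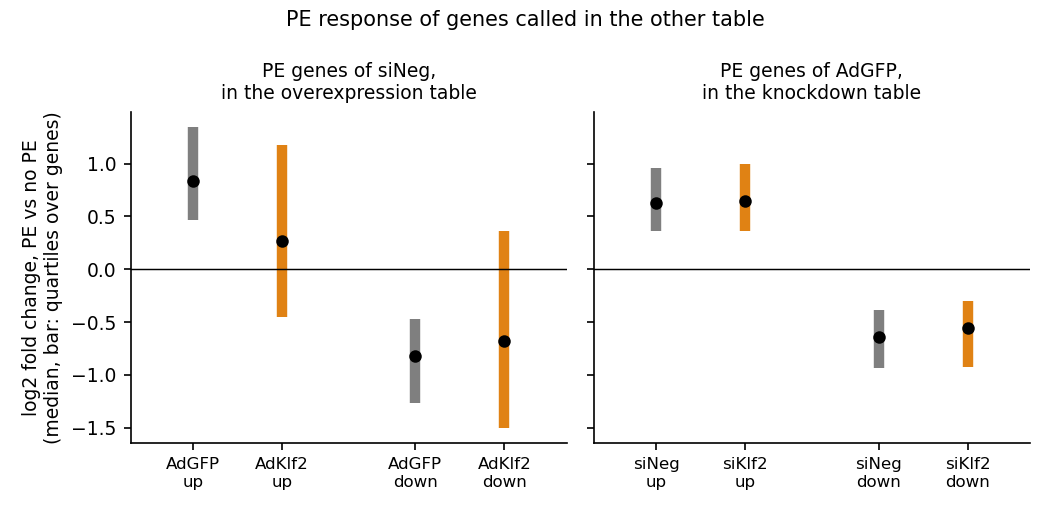
Median log2 fold change of PE against no PE (points) with quartiles over genes (bars) for PE-responsive genes called in the other table with a fold of at least 1.5, in control arms (grey) and in siKlf2 or AdKlf2 arms (orange). The 984 genes raised by PE in siNeg had medians of 0.83 in AdGFP and 0.26 in AdKlf2.

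Set against AdGFP rather than across PE, the same lists gave less uniform results. In AdKlf2 with PE, 4421 genes raised by PE in siNeg with no minimum fold had a median log2 fold change of -0.17, with 916 higher and 1171 lower by a fold of at least 1.5. Camera gave an adjusted p of 0.0619, which missed the threshold, and adjusted p = 0.146 with an estimated correlation. That estimate was 0.00986, so here too the larger p did not come from a higher correlation than the preset 0.01. For the 984 genes of that list with a fold of at least 1.5 the median was -0.40, with 225 higher and 359 lower (camera adjusted p = 0.00458, and adjusted p = 0.119 with an estimated correlation). In AdKlf2 without PE, the median of those 984 genes was 0.19, in the opposite direction, with 211 higher and 51 lower (camera adjusted p = 0.000611, and adjusted p = 0.119 with an estimated correlation). The 4301 genes lowered by PE in siNeg had a median of -0.03 and a mean of 0.16 in AdKlf2 with PE. There 1205 were higher and 1106 lower, and camera gave an adjusted p of 0.738. In AdKlf2 without PE these 4301 genes had a median of -0.13, against 0.04 for other genes, with 397 higher and 446 lower. Camera gave an adjusted p of 0.0161 for that comparison, and adjusted p = 0.146 with an estimated correlation.

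Knockdown and overexpression were then compared gene by gene. With PE, 365 genes were higher in siKlf2 and lower in AdKlf2, against 222 for independent lists, and 592 were lower in siKlf2 and higher in AdKlf2, against 477. A further 231 genes were higher in both, against 269, and 410 lower in both, against 393. Fisher's exact test gave adjusted p of 1.11e-25, 3.49e-10, 0.00582 and 0.323 for these overlaps. The test treats genes as independent and equally likely to be called, which these genes need not be. Of the 1598 genes called in both comparisons with a fold of at least 1.5, 957 moved in opposite directions and 641 in the same direction. Without PE, overlaps exceeded those of independent lists in every direction, so such an excess alone does not show opposite change. They were 140 genes higher in both against 99.7, 133 lower in both against 97.7, 73 higher in siKlf2 and lower in AdKlf2 against 49.97, and 320 lower in siKlf2 and higher in AdKlf2 against 195. The Spearman correlations of the fold changes across genes were -0.0939 with PE and -0.00132 without PE. With no minimum fold, 5189 genes lowered by AdKlf2 with PE had a median log2 fold change of 0.03 in siKlf2 with PE. For other genes it was -0.08. Camera gave an adjusted p of 0.0231, and 0.125 with an estimated correlation. For 5258 genes raised by AdKlf2 with PE the median was -0.06 against -0.03 (camera adjusted p = 0.499). Neither list passed at a fold of at least 1.5 (camera adjusted p = 0.113 and 0.149), and none passed without PE.

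**Figure D5:**
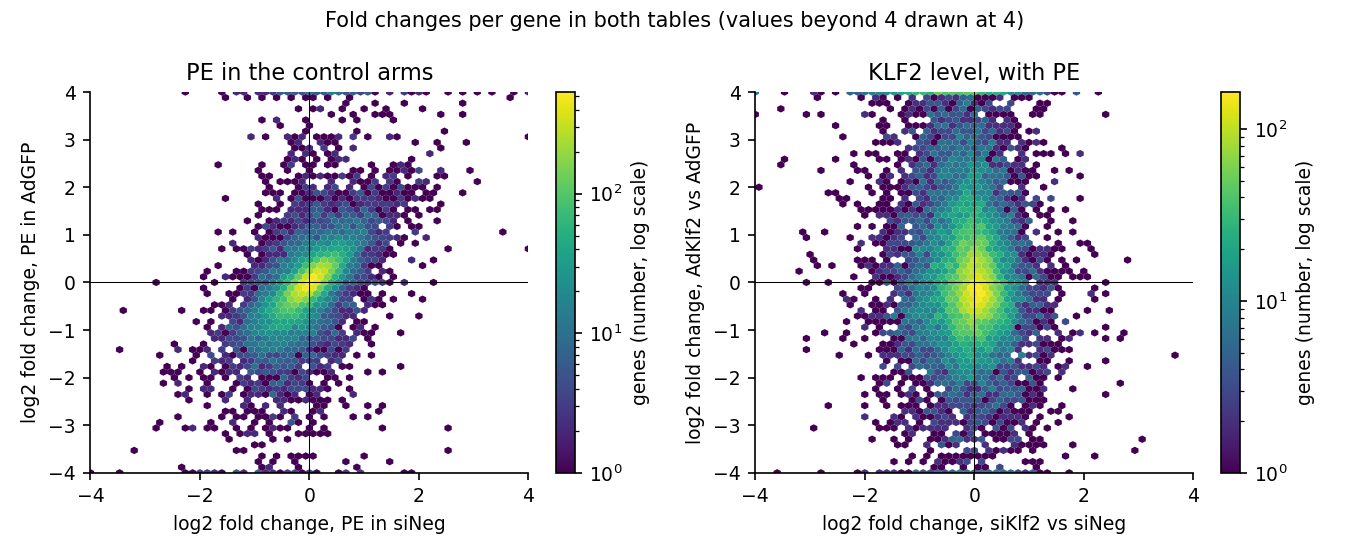
Log2 fold changes of 15944 genes in the knockdown table (horizontal axes) and the overexpression table (vertical axes), coloured by the number of genes on a log scale, with values beyond 4 drawn at 4. The PE responses of the control arms lie along a diagonal (Spearman correlation 0.632), and the changes with KLF2 level under PE do not (Spearman correlation -0.0939).

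The CUT&Tag peak list held 3065 peaks, from 1 library with no control library used here. On assembled chromosomes of the mRatBN7.2 build lay 2647 peaks (86.4%, 95% Wilson interval 85.1 to 87.5). A further 417 lay on unplaced contigs (13.6%, 95% Wilson interval 12.4 to 14.9) and 1 on the mitochondrial genome. These intervals treat peaks as independent draws and measure no spread between libraries. Peaks had a median width of 431 bp (quartiles 308 and 608) and a median fold enrichment of 4.48 (quartiles 3.64 and 5.59), as given in the authors' list. Chromosome 1 held the most peaks, 352, while chromosome X held 51 and chromosome Y 7. Among peaks on assembled chromosomes, the highest fold, 24.6, was that of a peak on chromosome 4 from 182684957 to 182685476, followed by 23.2 on chromosome 13 from 369 to 2023 and 20 on chromosome 8 from 37134076 to 37134376. Of the 10 peaks with the highest fold on assembled chromosomes, 3 lay within the first 4000 bp of a chromosome, on chromosomes 13, 14 and 15. The mitochondrial peak spanned 16034 bp at a fold of 1.71. No peak was assigned to a gene, since no gene annotation of this build was used here.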

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

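Tests of regroupings, of depth and of the number of RNA molecules were set before their results were seen, whereas the tests of scaling, of noise, of low counts set to 0 and of the tables' comparability were chosen after the result was seen.

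The PE response differed between siKlf2 and siNeg for 2622 genes and between AdKlf2 and AdGFP for 7926 genes, by the interaction term of edgeR's fit. The same term passed for ENSRNOG00000008141 at a log2 difference of -2.44 in the knockdown table and -5.91 in the overexpression table. The IDs were chosen for large PE responses in the control arms, so a difference toward a smaller response in the other arm is partly built in. The term passed for ENSRNOG00000008176 at -1.78 and -0.61, and for ENSRNOG00000019120 at -0.60 and 3.4. For ENSRNOG00000012442 it passed in the knockdown table at 0.44, and there it was lost without siNeg replicate 2 (edgeR adjusted p = 0.0988), without siKlf2 replicate 1 (edgeR adjusted p = 0.0853), without siKlf2 with PE replicate 2 (edgeR adjusted p = 0.105) and with DESeq2 (adjusted p = 0.0584). The knockdown count moved both down and up when a library was left out, in fits that keep 1 library in a group. Such fits cannot tell a loss of libraries from the weight of a particular one.

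Among 50 drawn regroupings of the 12 overexpression libraries, the real one included, only 1, the real one, gave as many interaction genes. It called 7926 genes, against 5035 in the highest other. These regroupings also mixed libraries that differ in KLF2 level and PE, so they cannot exclude chance for the interaction itself. For AdKlf2 against AdGFP the 10 splits are too few for a share under 0.05. The real split, 1 of 10, called 5672 genes without PE, with 0 in the highest other split, and 10625 with PE, with 0 in the highest other. For PE the real split called 5588 genes in AdGFP, with 2 in the highest other, and 9895 in AdKlf2, with 0 in the highest other.

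AdKlf2 changed more genes with PE than without. With every library thinned to the smallest total, 5675 genes were called without PE and 10569 with PE, and the interaction counted 7946. These values argue against a difference in total counts as the cause. Thinning cannot make up for fewer RNA molecules sampled in AdGFP without PE, so it does not exclude that. The lower count with RLE factors or library totals alone was 7844, so the count did not rest on the choice between these scalings. The share of interaction genes called higher moved from 51.1% to 54.7% with RLE factors and 46.9% with library totals. An error common to all these scalings was not tested. Among 2222 genes of at least 100 CPM the median absolute fold change on the log2 scale was 2.75 times as large with PE (0.56) as without (0.20), which argues against noise of the AdGFP libraries as the whole cause. A different level of the transgene with PE and a biological effect of PE on KLF2 action both stay open, as neither was tested.

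AdGFP libraries without PE held few genes at low counts. After thinning, their highest value was 1377 genes with 1 to 5 counts, against at least 1810 in the others, and they had 16171 to 16710 detected genes against 17056 to 18176. The gap was smaller than the 1.5-fold bound set beforehand, so depth was set aside only on the separation of all libraries, which was judged afterwards. At 0 in one AdGFP library and at 50 counts or more in another were 188 genes, against at most 10 in other groups. This cannot tell whether low counts had been set to 0, as a high spread between libraries could also give such genes. The AdGFP libraries still held 539 to 776 genes with 1 to 5 counts, so low counts had not all been set to 0. A variance over mean of 18.6 at 16 to 64 counts, against 4.23 to 4.84 in the other groups, is consistent with fewer RNA molecules sampled in these libraries, while slopes over the mean count of 0.027 to 0.112 in the 4 groups did not set AdGFP apart, and no biological explanation was tested.

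Knockdown and overexpression fold changes with PE were only weakly opposite across genes, with a Spearman correlation of -0.0939. Genes higher in siKlf2 and lower in AdKlf2 (365 against 222) and the reverse (592 against 477) outnumbered those of independent lists. With PE, genes higher in both (231 against 269) fell short of independent lists, and genes lower in both (410 against 393) were close to them. Without PE, overlaps in the same direction exceeded independent lists too, so an excess alone does not show opposite change. Genes are not independent, so chance was not excluded. Fold changes without and with PE correlated across genes at 0.505 or more inside each table, which argues against noise, and the PE responses of both tables at 0.632, which argues against tables that are not comparable. Among genes called in both comparisons 59.9% moved in opposite directions, an excess over independent lists that stays far from a general opposite change hidden among unchanged genes. The size of the knockdown and of the overexpression was not checked and stays open. The different timing of small interfering RNA and virus, and a biological asymmetry between loss and excess of KLF2, stay open too and were not tested.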

How the results depend on the processing

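Library totals alone, voom weights, fry, RLE factors for the lists, halved counts, the minimum of 10 CPM and both peak alternatives were chosen after the data were seen, and the other alternatives before that.

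All 10 counts of called genes stayed within 1.5-fold with RLE factors, no filter, DESeq2, voom weights, halved counts and, where run, fits of only 2 groups. With a replicate block, which the numbering does not justify, they were 9742 and 9838 for siKlf2 without and with PE, 8932 and 8726 for PE in siNeg and siKlf2, 2622 for the knockdown interaction, 5555 and 10501 for AdKlf2 without and with PE, 5469 and 9795 for PE in AdGFP and AdKlf2, and 7832 for the overexpression interaction. A fold of at least 1.5, by construction, lowered them to 3152, 3265, 2523, 2495, 447, 2546, 2254 and 6441 for siKlf2 without and with PE, PE in siNeg, PE in siKlf2, the knockdown interaction, AdKlf2 without PE, PE in AdGFP and PE in AdKlf2. Leaving out a library gave 1553 to 3312 genes for the knockdown interaction, and the other 9 counts stayed within 1.5-fold.

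The list raised by PE in siNeg passed in AdKlf2 with PE at a fold of at least 1.5 (camera adjusted p = 0.00458), but not when that list was tested with an estimated correlation (adjusted p = 0.119). With no minimum fold it passed with fry (adjusted p = 0.000308), which tests no contrast with other genes. Fry also passed for the list lowered by PE in siNeg (adjusted p = 2.78e-05). The list lowered by PE in AdGFP was lost in siKlf2 with PE with an estimated correlation (camera adjusted p = 0.125). The cause was not tested.

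The correlation between KLF2 changes was -0.0893 without PE as Pearson's r, and with PE -0.155 as Pearson's r and -0.113 at a mean log2 CPM of at least 5. The PE correlation was 0.505 as Pearson's r, 0.80 at a mean log2 CPM of at least 5, 0.784 at 10 CPM and 0.685 with halved counts. With a library left out it was 0.571 to 0.618. The filter on low counts was run again for each such fit, so the genes compared can differ and these values do not isolate single libraries. The cause was not tested.

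With library totals alone, ENSRNOG00000019120 reversed in siKlf2 with PE (log2 fold change -0.23). ENSRNOG00000012442 was called in siKlf2 with PE with RLE factors (adjusted p = 0.0374), without a filter (adjusted p = 0.0013), with only 2 groups (adjusted p = 0.041) and at 10 CPM (adjusted p = 0.048), and lost without PE with DESeq2 (adjusted p = 0.152). With library totals alone the median log2 fold change of all genes moved to -0.22 and -0.30 for siKlf2 without and with PE, -0.12 and -0.19 for PE in siNeg and siKlf2, -0.13 for AdKlf2 with PE, and -0.15 and -0.21 for PE in AdGFP and AdKlf2. The share of peaks on unplaced contigs was 18.5% in the upper part by q and 12.2% at a fold of at least 5. The gene list, promoter and motif alternatives were not run. Depth sets no exact limit for genes at 0 counts, since fragments may be counted at both mates.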

Other observations

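The hypothesis and the tests without PE were chosen after the result was seen, whereas the set tests with PE and their estimated correlation had been planned.

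A hypothesis from the comparisons is that KLF2 holds down genes that PE induces. With PE, genes of the other table raised by a fold of at least 1.5 had a higher median after knockdown and a lower median after overexpression, but with an estimated correlation the adjusted p was 0.0598 and 0.119, so the data leave this open. Without PE, the median log2 fold change was 0.20 after knockdown, the direction the hypothesis needs, and 0.19 after overexpression, the opposite direction. With an estimated correlation the adjusted p was 0.0598 and 0.119, and the overexpression value uses the AdGFP libraries that stood apart, so this too stays open. The longer list with no minimum fold passed after knockdown with and without PE, with an adjusted p of 0.00867 in each, and missed the threshold after overexpression with PE (adjusted p = 0.146) and without PE (adjusted p = 0.193, median 0.07, the opposite direction), all with an estimated correlation.

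A set of 28 genes had 0 counts in all AdGFP libraries without PE and at least 1 CPM in each AdKlf2 library without PE, with a median of 2.47 CPM there. The AdGFP libraries lacked genes at low counts, so 0 counts in them set no limit, and no fold is given. In the other direction there were 0 such genes. Among genes with at least 200 counts over a pair of replicates, at most 0.453% had identical counts. No library was therefore a copy of another of its group, and pairs across groups were not checked.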
